A study of Homo sapiens with 6 samples.

How the data were processed

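RNA was measured in 6 libraries of NCI-H1299 cells, a human lung cancer cell line, 3 from wild type cells and 3 from cells that carried an mCherry-tagged MTSS1 expression plasmid. Per the labels' protocols, the plasmid-bearing cells were selected with hygromycin and sorted by flow cytometry, and the same text mentions HEK293T cells in connection with the transfection. Poly(A) RNA was made into libraries with a directional kit and sequenced as single reads of 50 cycles, per the labels' protocols. The replicates are those the labels give. Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these libraries.

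The deposited table holds raw whole-number read counts per Ensembl gene for 64253 identifiers. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and processed with HISAT2 2.1.0, HTSeq and the GRCh38 build. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies, histone genes among them, are uncertain. Symbols were found for 41454 identifiers, of which 459 came from GENCODE release 29 because the current name table lacked the identifier. Coordinates, gene types, transcript length and GC content came from GENCODE release 29 on GRCh38. Of the 16091 genes tested, 14869 had a symbol and 15883 had coordinates.

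Most genes of the major histocompatibility complex were listed at 0. Of 179 protein-coding genes between 28.5 and 33.5 Mb of chromosome 6, 141 (78.8%) had 0 counts in all 6 libraries, against 18.9% of the 19478 protein-coding genes elsewhere. Broadly expressed genes were hit too: DDX39B and FLOT1 had 0 counts, and RPS18 and TUBB had 1 count each over the 6 libraries. A count of 0 in this span, which holds TNF, LTB, IER3 and the HLA genes, is therefore a listed value and cannot be read as absence of expression. Low counts of broadly expressed genes were not confined to this span: RPS9 had 17 and 20 counts and B2M 34 and 23 over the wild type and overexpressing libraries, so a count near 0 elsewhere is also only a listed value. The span was chosen after its values were seen.

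Total counts per library ranged from 13883380 to 29479453. Intervals and floors below cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of replicates differed by more than sampling noise: chi-square per degree of freedom, over genes with at least 20 pooled counts, lay between 14.7 and 28 in all 6 pairs within groups, and no library was treated as a copy of another.

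Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. The steps were TMM scaling, the filterByExpr filter and edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. An adjusted p called edgeR adjusted p is from this test. Fold changes are those of MTSS1-overexpressing over wild type cells, and levels are in CPM, counts scaled to a common library size with TMM. The biological coefficient of variation was 0.162. Of a gene with 0 counts in every library of a group, the fold is given as a lower bound against a floor of 3 counts over that group, and with 1 to 3 counts as a ratio of pooled counts with its exact 95% interval.

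Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, two-sided, with adjustment over 25 lists. Camera was run again with the correlation estimated from these libraries. That run uses only the few residual degrees of freedom of the libraries, and the preset run does not. It therefore gives a larger p at equal correlation. The fry test of limma asks whether a list's genes move, on balance, one way, and does not compare the list with other genes. The 25 lists, the 2 groups, the tests and the rule for named genes were fixed before the data were examined. The rule picks MTSS1 and RELA, the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a symbol, a mean of at least 5 CPM and no overlap of CPM between the groups (pseudogenes and clone-based names left out), and up to 4 members of each list by smallest adjusted p (8 for the NF-κB target list). That gave 121 genes, of which 65 passed the threshold. Not all of them are named here. Other list members that are named were chosen after their values were seen.

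The titles of the libraries hold numbers that fall into 3 neighbouring pairs, each of 1 wild type and 1 MTSS1-overexpressing library. The labels do not say that neighbouring numbers share a day or a batch. Deviations from the group means correlated within these pairs at 0.66, 0.34 and 0.38 across genes. Between wild type and overexpressing libraries of different pairs the values lay between -0.4 and 0.1. Deviations sum to 0 within a group, so positive values within pairs push the others down and the contrast is partly fixed in advance. A fit with these pairs as a block, chosen before the data were seen, was run beside the unblocked one, and its counts are given beside the unblocked ones.

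Up to 50 nearest tested genes on the same chromosome (25 on each side where present) gave each gene's neighbour median of log2 fold change. In an alternative chosen after seeing the data, this median was put into the offsets of the overexpressing libraries, so that the test asked whether a gene differed from its neighbours. Genes with at least 2 CPM on average were scanned along each chromosome with running medians of 51 genes, against a limit set by 1000 permutations of gene order. Other alternatives were RLE size factors, no filter, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, leaving out each library in turn, and leaving out the 2 libraries with title numbers 2 and 3, the last chosen after seeing the data.

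The steps were tested on simulated counts for 16091 genes with the means, depths and spread of this comparison, of which 200 were changed. These 200 were drawn from genes above a minimum mean CPM, so the rates below leave out the lowest-expressed tested genes. Of 50 genes each, the test called 36% at 1.5-fold, 58% at 2-fold, 96% at 4-fold and 100% at 8-fold, all with the right sign. It also called 14 of 15891 unchanged genes (8.8% of its calls). A simulated list of 30 genes shifted by 0.5 gave a camera p of 1.3e-27 and an unchanged list 0.512, and both simulated chromosome segments of 80 genes were found with 0 false ones. Simulated genes were drawn independently of each other and without pairs of libraries. The simulation therefore does not show how camera behaves on lists whose members are correlated.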

Results

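Poly(A) RNA of NCI-H1299 cells was compared between wild type cells and cells overexpressing MTSS1 from a plasmid, with 3 libraries per group. No library came from cells with a control plasmid. Differences between the groups therefore cannot be told apart from effects of the tagged plasmid, the hygromycin selection or the sorting. MTSS1 is a membrane-binding scaffold protein of the I-BAR family that acts on the actin cytoskeleton. The wild type libraries held 19018751, 29479453 and 26736187 counts (replicates 1 to 3). The overexpressing libraries held 13883380, 25741708 and 25253250. The first principal component (34.8% of the variance) set wild type replicate 1 and MTSS1 overexpressing replicate 1 apart from the other 4 libraries. The second (32.9%) separated the 2 groups.

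MTSS1 (ENSG00000170873, chromosome 8, 124550790 to 124728429, GRCh38) was read first as a check of the labels. It stood at 24.2, 18.0 and 24.3 CPM in the wild type libraries and at 550, 544 and 568 CPM in the overexpressing libraries, a 25.1-fold rise (log2 fold change 4.65, SE 0.13, edgeR adjusted p = 3.6e-07, n = 3 per group). Counts do not separate plasmid-borne from endogenous MTSS1 transcripts. The study's title concerns the effect of MTSS1 on NF-κB activity through phosphorylation of RelA, the p65 subunit of NF-κB, which RNA counts do not measure. RELA itself (ENSG00000173039, chromosome 11, 65653596 to 65663094) stood at 113 ± 9.83 CPM in wild type and 112 ± 8.37 CPM in overexpressing cells (SD, n = 3). Its log2 fold change of -0.01 (SE 0.09, edgeR adjusted p = 0.97) did not pass the test.

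**Figure D1:**
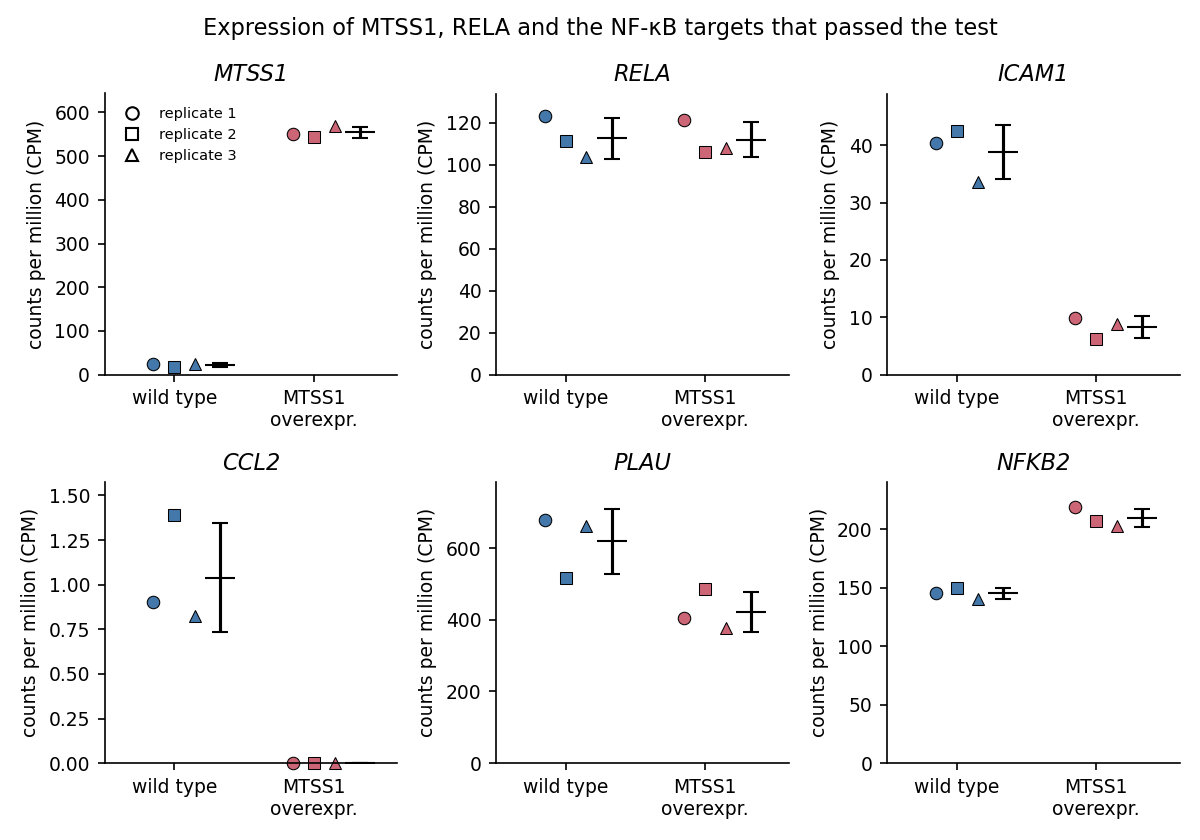
CPM (vertical axes, each starting at 0) of MTSS1, RELA and the 4 NF-κB target genes that passed the test, in 3 wild type (blue) and 3 MTSS1-overexpressing (red) libraries. Symbols mark replicates, and the black bars give the group mean ± SD. MTSS1 lies near 22.1 CPM in wild type and near 554 CPM in overexpressing cells, RELA overlaps between the groups, ICAM1, CCL2 and PLAU lie lower and NFKB2 lies higher in overexpressing cells.

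Between the 2 groups, 688 of 16091 genes changed, 293 higher and 395 lower in overexpressing cells (edgeR's quasi-likelihood test, adjusted p under 0.05). Of these, 201 changed at least 2-fold, 72 higher and 129 lower, and 652 were protein coding. Among changed genes with a mean of at least 5 CPM, the highest fold change was not that of MTSS1. TMTC1, a mannosyltransferase of the endoplasmic reticulum (chromosome 12, 29500840 to 29784759), rose from 0.372 ± 0.112 to 18.5 ± 1.6 CPM (SD, n = 3; log2 fold change 5.58, SE 0.22, edgeR adjusted p = 3.1e-06). AMPH, encoding the membrane-curving protein amphiphysin, rose by 2.85 on the log2 scale. The membrane-bound protease gene MMP17 rose by 2.32 and DPYSL5, a gene of neurite growth, by 2.21. GNAO1, encoding a G protein subunit, ARMCX4, the neuronal splicing regulator gene NOVA2 and the scaffold gene IQGAP2 rose by 1.85, 1.57, 1.55 and 1.53.

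Of the same genes, the lowest fold change was that of MYO10, the myosin motor of filopodia (ENSG00000145555, on chromosome 5). It had 1336 pooled counts in wild type and 3 in overexpressing cells, a ratio of 384 (exact 95% interval 131 to 1865; edgeR adjusted p = 3.1e-06). PDE10A, a cyclic nucleotide phosphodiesterase gene, fell from 38.6 ± 0.580 to 3.92 ± 3.05 CPM (SD, n = 3; log2 fold change -3.34, SE 0.58, edgeR adjusted p = 0.015). CYP24A1, which inactivates vitamin D, changed by -3.09, NEXMIF by -2.93, the neurotensin receptor gene NTSR1 by -2.87 and the leukocyte adhesion receptor gene ICAM1 by -2.24. The actin-binding coronin gene CORO2B, the receptor gene VIPR1, the scaffold gene MPP4 and the cell adhesion gene ALCAM changed by -2.12, -2.01, -1.86 and -1.82. Without 1 of the libraries, 16 of the 20 genes with the highest and lowest fold changes at this level passed the test in each of the 6 fits. The other 4 lost the call in at least 1 fit: NTSR1 (highest edgeR adjusted p 0.058, without wild type replicate 3), PDE10A (0.058; without wild type replicate 2 or 3), MMP17 (0.10; without any 1 wild type replicate) and CYP24A1 (0.12; without any 1 wild type replicate or MTSS1 overexpressing replicate 1). CYP24A1 also did not pass with the neighbour offset (log2 fold change -3.04, edgeR adjusted p = 0.067). MMP17 stood at 10.6, 29 and 7.49 CPM in the overexpressing libraries, and its log2 fold change was 1.52 without MTSS1 overexpressing replicate 2.

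The number of changed genes rested on the number of libraries and on the fit. With neighbouring title numbers as a block it was 3651 (1716 higher, 1935 lower), all 688 among them. With 1 library left out it lay between 145 (without wild type replicate 3) and 346 (without wild type replicate 2), with 341 without wild type replicate 1 and 325, 250 and 195 without MTSS1 overexpressing replicates 1, 2 and 3. Without both libraries that stood apart on the first component it was 132.

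Transcripts of NF-κB target genes, which bear on the question the study's title raises, moved in both directions. Of 43 listed genes, 29 had enough counts to be tested: 1 was higher, 3 were lower and 25 did not pass the test (also 1 and 3 adjusted over the list alone; 3 and 6 with the block). ICAM1 (ENSG00000090339, chromosome 19, 10270835 to 10286615) fell from 38.8 ± 4.72 to 8.29 ± 1.93 CPM (SD, n = 3; log2 fold change -2.24, SE 0.18, edgeR adjusted p = 9.3e-04). The chemokine gene CCL2 (ENSG00000108691, chromosome 17) had 81 counts in wild type and 0 in overexpressing cells, at least 23.3-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0099). PLAU, encoding the urokinase plasminogen activator, fell from 619 ± 90.2 to 422 ± 56.2 CPM (edgeR adjusted p = 0.047). NFKB2, which encodes the p100 and p52 subunits and is itself an NF-κB target, rose from 145 ± 4.98 to 210 ± 8.03 CPM (log2 fold change 0.53, SE 0.07, edgeR adjusted p = 0.0075).

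Other well-known targets did not pass the test. The inhibitor gene NFKBIA had a log2 fold change of 0.29 (edgeR adjusted p = 0.40), TNFAIP3 of 0.07 (edgeR adjusted p = 0.87) and RELB of 0.18 (edgeR adjusted p = 0.48). The apoptosis inhibitor gene BIRC3 stood at 164 ± 43.3 and 246 ± 82.0 CPM (edgeR adjusted p = 0.25; 9.9e-05 with the block). SOD2 stood at 176 ± 11.1 and 146 ± 16.5 CPM (edgeR adjusted p = 0.18; 0.0034 with the block), and the median of its 50 neighbours was -0.18. The list's median log2 fold change was 0.10 and its mean -0.28 (0.10 and -0.18 with CCL2 at its bound). The camera test pointed down with p = 0.83, so that median and test differ in sign (camera adjusted p = 0.90; adjusted p = 0.998 with an estimated correlation). Of the 14 members with too few counts, CXCL8 had 3 and 5 counts in the wild type and overexpressing libraries, VCAM1 4 and 16, BCL2A1 16 and 2, IL1B 8 and 0, CCL20 5 and 1, CX3CL1 3 and 0, and IL1A and CXCL5 1 and 0 each. IL6, CSF2 and CXCL10 were listed at 0 in all 6 libraries. TNF, LTB and IER3 were listed at 0 too, but they lie in the span of chromosome 6 where most genes are, so their levels cannot be read. The PLAU call was lost without any 1 library except wild type replicate 2 (highest edgeR adjusted p 0.155). The NFKB2 call was lost without wild type replicate 3 (edgeR adjusted p = 0.0501), while ICAM1 and CCL2 passed in all 6 such fits.

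Of 29 tested genes of the NF-κB signalling machinery, 2 were higher and 1 lower (2 and 2 adjusted over the list alone; 3 and 5 with the block), with a camera adjusted p of 0.83. Besides NFKB2, the kinase gene IRAK1 rose from 549 ± 46.7 to 881 ± 85.7 CPM (log2 fold change 0.68, edgeR adjusted p = 0.0090) and the adaptor gene TAB2 changed by -0.50 (edgeR adjusted p = 0.038). The 50 neighbours of IRAK1 on the X chromosome had a median of 0.73 and those of TAB2 on chromosome 6 a median of -0.25. Neither gene passed the test against its neighbours (edgeR adjusted p = 0.88 and 0.32), where IRAK1 had a log2 fold change of -0.05. Without 1 library both calls were lost at least once, IRAK1 without wild type replicate 3 (edgeR adjusted p = 0.0502) and TAB2 in 4 of 6 fits (highest 0.14).

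MTSS1 and its family act on actin, and 40 genes of I-BAR proteins and actin regulators were tested. Besides MTSS1, the actin crosslinker gene FLNA rose from 1898 ± 213.3 to 3261 ± 471.1 CPM (log2 fold change 0.78, edgeR adjusted p = 0.012) and the actin elongation factor gene EVL by 0.41 (edgeR adjusted p = 0.041). In all, 3 were higher and 0 lower (3 and 3 adjusted over the list alone; 4 and 9 with the block). The camera adjusted p was 0.83. FLNA lies on the X chromosome among neighbours with a median of 0.71, and it did not pass the test against them (edgeR adjusted p = 0.85 with the neighbour offset). EVL lost its call with that offset (log2 fold change 0.32, edgeR adjusted p = 0.14) and in each of the 6 fits that left out 1 library (highest 0.16), and FLNA without wild type replicate 3 (edgeR adjusted p = 0.055).

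The list of matrix proteases and their inhibitors passed camera with the preset correlation and not with an estimated one (adjusted p = 0.0039 and 0.37). The estimated correlation of this list was -0.0043, below the preset 0.01, so higher correlation between its members does not explain the lost call. Camera with an estimated correlation also rests on the few residual degrees of freedom of these libraries, which raises p at equal correlation. Of 24 tested, 0 were higher and 4 lower (0 and 11 adjusted over the list alone; 0 and 13 with the block), with a median log2 fold change of -0.35. MMP17, which rose, is not on the list. With the preset correlation the camera adjusted p lay between 0.0016 and 0.014 when 1 library was left out. MMP14, the membrane-bound collagenase, fell from 115 ± 15.1 to 53.0 ± 3.63 CPM (log2 fold change -1.12, SE 0.11, edgeR adjusted p = 0.0016), while the median of its neighbours on chromosome 14 was 0.31. The interstitial collagenase gene MMP1 fell from 7.85 ± 2.67 to 1.94 ± 1.33 CPM (edgeR adjusted p = 0.046), ADAM12 from 1.20 ± 0.312 to 0.138 ± 0.148 CPM (edgeR adjusted p = 0.045), and PLAU is the 4th. MMP14 passed in all 6 fits without 1 library, whereas MMP1 and ADAM12 lost the call in 5 of them (highest edgeR adjusted p 0.15 for each). With the neighbour offset MMP14 passed, and ADAM12, PLAU and MMP1 did not (edgeR adjusted p = 0.064, 0.053 and 0.10), though their log2 fold changes of -3.35, -0.60 and -1.77 stayed near those without it.

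Epithelial and mesenchymal genes gave no single direction. Among 21 epithelial junction genes, 0 were higher and 1 lower (0 and 3 adjusted over the list alone; 1 and 4 with the block; camera adjusted p = 0.46). This gene, KRT8, encoding the keratin of simple epithelia, fell from 165 ± 41.2 to 49.6 ± 19.2 CPM (log2 fold change -1.74, edgeR adjusted p = 0.011). Its partner KRT18 stood at 522 ± 105.2 and 299 ± 88.3 CPM (edgeR adjusted p = 0.061; 4.4e-06 with the block). Among 24 mesenchymal genes, 4 were higher and 2 lower (4 and 2 adjusted over the list alone; 6 and 5 with the block; camera adjusted p = 0.90). The collagen gene COL6A1 rose by 0.69 (edgeR adjusted p = 0.014) and the smooth muscle actin gene ACTA2 by 0.70 (edgeR adjusted p = 0.024), and COL6A2 and FN1 were the other higher genes. The matrix protein gene SPARC (log2 fold change -1.80, edgeR adjusted p = 0.022) and PRRX1 (-0.50, edgeR adjusted p = 0.027) were lower. The KRT8 call was lost without MTSS1 overexpressing replicate 3 (edgeR adjusted p = 0.055). Without 1 library, COL6A1 lost its call in 3 of 6 fits, SPARC in 4 and ACTA2 and PRRX1 in all 6 (highest edgeR adjusted p 0.072, 0.086, 0.089 and 0.11). With the neighbour offset PRRX1 changed by -0.19 and did not pass (edgeR adjusted p = 0.43). COL6A2 and FN1 did not pass either (edgeR adjusted p = 0.074 and 0.081), with log2 fold changes of 0.50 and 0.51 against 0.60 and 0.57 without the offset.

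MTSS1 has been linked to Hedgehog signalling. Of 12 genes of that pathway tested, 2 were higher and 0 lower (2 and 0 adjusted over the list alone; 2 and 1 with the block; camera adjusted p = 0.57). The transcription factor gene GLI3 rose from 10.9 ± 1.77 to 30.2 ± 3.23 CPM (log2 fold change 1.47, SE 0.15, edgeR adjusted p = 0.0018) and kept its call in each of the 6 fits without 1 library and with the neighbour offset (edgeR adjusted p = 0.0024). The receptor gene SMO rose by 0.57 (edgeR adjusted p = 0.023; neighbour median 0.27, edgeR adjusted p = 0.23 with the offset) and lost its call in 5 of those fits (highest 0.10). GLI1, a target gene of the pathway, stood at 2.32 ± 0.516 and 3.18 ± 0.0756 CPM (edgeR adjusted p = 0.37).

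Among 25 interferon response genes, 1 was higher and 1 lower (2 and 2 adjusted over the list alone; 2 and 5 with the block; camera adjusted p = 0.53). SAMD9L rose by 0.85 (edgeR adjusted p = 0.015), and the antiviral gene MX1 stood at 0.724 ± 0.406 and 0.0896 ± 0.0225 CPM (edgeR adjusted p = 0.039). Of 15 antigen presentation and immune checkpoint genes, 1 was higher, the peptide-trimming enzyme gene ERAP1 with a log2 fold change of 0.37 (edgeR adjusted p = 0.042), and 0 were lower (1 and 0 adjusted over the list alone; 3 and 3 with the block; camera adjusted p = 0.46). Another 10 members of this list, among them TAP1, PSMB8 and HLA-C, lay untested in the chromosome 6 span where most genes are listed at 0. Without 1 library, SAMD9L lost its call in 2 of 6 fits (wild type replicate 3 and MTSS1 overexpressing replicate 3, highest edgeR adjusted p 0.071), and MX1 and ERAP1 in all 6 (highest 0.14 for each). None of the 3 passed with the neighbour offset (edgeR adjusted p = 0.051, 0.055 and 0.18), where their log2 fold changes were 0.68, -2.96 and 0.26.

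The cell cycle list passed the camera test with a preset correlation. Of its 37 genes, 3 were higher and 1 lower (4 and 1 adjusted over the list alone; 19 and 1 with the block), with a median log2 fold change of 0.15 and a camera adjusted p of 0.011 (adjusted p = 0.79 with an estimated correlation). The mitotic kinase gene AURKB rose by 0.57 (edgeR adjusted p = 0.0098), the replication helicase gene MCM7 by 0.42 (edgeR adjusted p = 0.024) and the cyclin gene CCNE1 by 0.83 (edgeR adjusted p = 0.027). CDKN1A, which encodes the cell cycle inhibitor p21, fell from 49.2 ± 4.03 to 27.7 ± 1.75 CPM (log2 fold change -0.83, SE 0.10, edgeR adjusted p = 0.0044). CDKN1A was called in all 6 fits without 1 library and with the neighbour offset, while AURKB, MCM7 and CCNE1 lost theirs in 1, 6 and 4 of those fits (highest edgeR adjusted p 0.057, 0.094 and 0.092). With the offset AURKB, MCM7 and CCNE1 had log2 fold changes of 0.28, 0.37 and 0.72 and did not pass (edgeR adjusted p = 0.15, 0.051 and 0.068).

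Of 12 replication-dependent histone genes, 4 were higher and 0 lower (6 and 1 adjusted over the list alone; 6 and 1 with the block), with a median of 0.51 and a camera adjusted p of 0.011 (adjusted p = 0.79 with an estimated correlation). This list and that of the mitochondrial transcripts were fixed as checks of other cell types or RNA quality. A link of the histone counts in these poly(A) libraries to the cell cycle was not tested. H2BC5, H2BC12, H2BC21 and H2AC6 rose by 0.86, 0.74, 1.12 and 0.69 (edgeR adjusted p between 0.0081 and 0.017), though reads shared between near-identical histone genes make single members uncertain. H2BC5 kept its call in all 6 fits without 1 library, and the other 3 lost theirs in 2 or 3 (highest edgeR adjusted p 0.078). The mitochondrial genome gave 4.37, 3.62 and 5.08% of the counts in the wild type and 4.56, 5.07 and 5.65% in the overexpressing libraries, so the groups overlapped. All 13 mitochondrially encoded transcripts had fitted changes above 0, with a median of 0.36 and a camera adjusted p of 0.0039 (adjusted p = 0.79 with an estimated correlation). With an estimated correlation of 0.73, these transcripts are not 13 independent measurements. None of them passed edgeR's test (6 had an unadjusted p under 0.05), also 0 adjusted over the list alone, and 12 passed with the block. MT-CO2, the member with the smallest p, stood at 2367 ± 329.8 and 3172 ± 321.2 CPM (edgeR adjusted p = 0.085). Without wild type replicate 2 or MTSS1 overexpressing replicate 3, the cell cycle list (camera adjusted p = 0.39 and 0.083) and the mitochondrial list (0.093 and 0.083) did not pass. The histone list did not pass without wild type replicate 1 (0.14) or MTSS1 overexpressing replicate 3 (0.21).

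**Figure D2:**
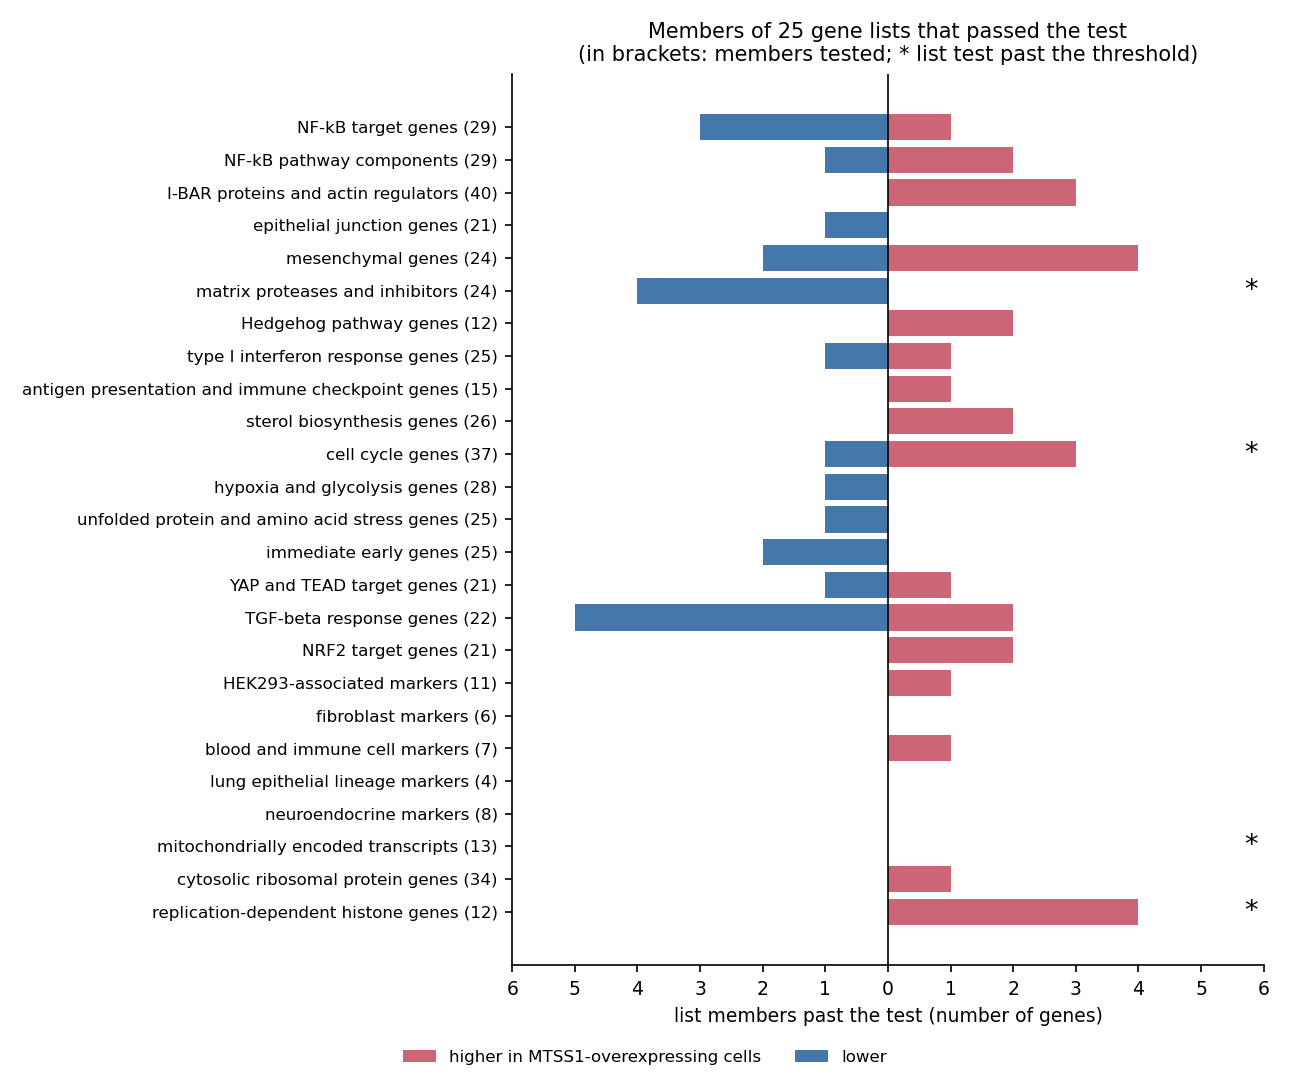
Number of members of each of 25 gene lists that were higher (red, to the right) or lower (blue, to the left) in MTSS1-overexpressing cells, by edgeR's quasi-likelihood test at an adjusted p under 0.05. The number tested stands in brackets and a star marks the 4 lists past the camera test with a preset correlation. None of these 4 passed with an estimated correlation, where few residual degrees of freedom also raise p. No list had more than 5 members on 1 side.

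None of the signalling lists passed camera. Of 22 TGF-β response genes, 2 were higher and 5 lower (4 and 7 adjusted over the list alone; 4 and 10 with the block; camera adjusted p = 0.33). The binding protein genes LTBP2 and LTBP3 changed by -0.54 and -0.72 (edgeR adjusted p = 0.011 and 0.022) and the BMP-responsive gene ID3 by 0.96 (edgeR adjusted p = 0.025), and each lost its call in 2 to 4 of the 6 fits without 1 library (highest 0.090). Of 21 YAP and TEAD targets, 1 was higher and 1 lower (2 and 2 adjusted over the list alone; 5 and 6 with the block; camera adjusted p = 0.99). NUAK2 rose by 0.79 (edgeR adjusted p = 0.039), lost in 5 of those fits (highest 0.14) and with the neighbour offset (log2 fold change 0.75, edgeR adjusted p = 0.070). NT5E, the ectonucleotidase CD73, fell from 1481 ± 283.2 to 733 ± 27.3 CPM (log2 fold change -1.01, SE 0.13, edgeR adjusted p = 0.0044), called in all 6. Of 25 immediate early genes, 0 were higher and 2 lower (0 and 4 adjusted over the list alone; 5 and 9 with the block; camera adjusted p = 0.33). SPRED1 and DUSP6, both brakes of MAP kinase signalling, changed by -0.49 and -0.55 (edgeR adjusted p = 0.018 and 0.029), each lost in 5 of those fits (highest 0.085 and 0.10). SPRED1 lies on chromosome 15 with a neighbour median of -0.22 and did not pass with the neighbour offset (log2 fold change -0.27, edgeR adjusted p = 0.18), whereas DUSP6 passed (-0.55, edgeR adjusted p = 0.043).

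Stress and metabolic lists did not pass either. Of 25 unfolded protein and amino acid stress genes, 0 were higher and 1 lower (1 and 1 adjusted over the list alone; 2 and 7 with the block; camera adjusted p = 0.53). EDEM1, which acts in degradation of misfolded proteins, changed by -1.11 (edgeR adjusted p = 0.0050) and was called in all 6 fits without 1 library. Of 28 hypoxia and glycolysis genes, 0 were higher and 1 lower (0 and 0 adjusted over the list alone; 5 and 4 with the block; camera adjusted p = 0.46). ANGPTL4 changed by -1.42 (edgeR adjusted p = 0.0496), lost in 5 of those fits (highest 0.16) and with the neighbour offset (log2 fold change -1.39, edgeR adjusted p = 0.080). Of 26 sterol biosynthesis genes, 2 were higher and 0 lower (2 and 0 adjusted over the list alone; 3 and 4 with the block; camera adjusted p = 0.53). Of 21 NRF2 targets, also 2 were higher and 0 lower (2 and 0 adjusted over the list alone; 5 and 5 with the block; camera adjusted p = 0.57). NSDHL rose by 0.79 (edgeR adjusted p = 0.0085) and was called in all 6 fits. It lies on the distal X chromosome with a neighbour median of 0.61, and did not pass the test against these neighbours (edgeR adjusted p = 0.53 with the neighbour offset). The other higher sterol gene, INSIG1, and the NRF2 target PGD changed by 0.43 and 0.34 and lost their calls in all 6 fits (highest edgeR adjusted p 0.12 and 0.15). With the offset these 2 changed by 0.20 and 0.25 and did not pass (edgeR adjusted p = 0.37 and 0.17).

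Markers of other cell types were compared between the groups, which cannot show a second population present in both. Of 11 HEK293-associated markers, 1 was higher, the neurofilament gene NEFH with a log2 fold change of 0.65 (edgeR adjusted p = 0.019), and 0 were lower (1 and 1 adjusted over the list alone; 2 and 2 with the block; camera adjusted p = 0.83). Of 7 blood and immune markers, 1 was higher, the integrin gene ITGAM with 3.57 ± 0.389 and 8.16 ± 1.89 CPM (edgeR adjusted p = 0.021), and 0 were lower (1 and 0 adjusted over the list alone; 1 and 0 with the block; camera adjusted p = 0.99). Without 1 library, NEFH lost its call in 4 of 6 fits and ITGAM in 5 (highest edgeR adjusted p 0.067 and 0.089). None of 6 fibroblast, 4 lung epithelial lineage and 8 neuroendocrine markers passed edgeR's test, also 0 adjusted over the list alone (camera adjusted p = 0.46, 0.57 and 0.33; with the block 0, 1 and 3 passed, and 0, 1 and 3 had an unadjusted p under 0.05). KRT14, KRT5 and the blood marker HBB had 0 counts in wild type replicate 1 and MTSS1 overexpressing replicate 1. In the other libraries they had 16 to 41, 25 to 53 and 6 to 17 counts. The lung markers NKX2-1 and ABCA3 and the blood markers ITGAM, CD68 and PTPRC were counted in all 6 libraries. Of 34 cytosolic ribosomal protein genes, 1 was higher, RPL10 on the distal X chromosome with a log2 fold change of 0.89 (edgeR adjusted p = 0.0032; 0.40 with the neighbour offset), and 0 were lower (1 and 0 adjusted over the list alone; 5 and 4 with the block; camera adjusted p = 0.68).

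Across the lists, median, mean and camera direction differed in sign in 6 of 25: NF-κB targets, I-BAR and actin genes, mesenchymal genes, Hedgehog genes, YAP and TEAD targets and blood markers. Of the 4 lists past camera with the preset correlation, the estimated correlation was -0.0043 for matrix proteases and 0.44 for cell cycle genes. It was 0.31 for histone genes and 0.73 for mitochondrial transcripts. None of the 25 passed camera with an estimated correlation (smallest adjusted p 0.37, with 1 list, the matrix proteases, at an unadjusted p under 0.05). With the few residual degrees of freedom of that run a pass was hard at any correlation. The lost calls therefore do not show that correlation alone lies behind the preset ones. None passed fry's directional test (smallest adjusted p 0.060; 3 lists at an unadjusted p under 0.05), while 19 passed fry's mixed test, which asks for change in either direction.

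Changed genes were grouped along the chromosomes, a scan chosen after the data were examined. Running medians of 51 genes passed the permutation limit of 0.17 in 22 segments, 10 higher and 12 lower in overexpressing cells, with a largest running median of 0.69 against 0.21 in 1000 permutations of gene order (p = 0.001, the smallest that these can give). The segments held 22.9% of the 12491 genes scanned and 51.6% of the called ones (320 of 620). Of these, 293 lay in a single segment and 282 of them had its sign. The other 27 lay on the X chromosome, where segments of opposite direction overlap. Segments and calls come from the same fold changes, so these shares describe the segments and do not test the grouping. On the X chromosome from 119.9 to 156.0 Mb the median log2 fold change of 133 genes was 0.51, with 46 genes called higher and 9 lower, IRAK1, FLNA, NSDHL and RPL10 among the higher ones. Along chromosome 15, from 20.4 to 101.7 Mb, the median of 384 genes was -0.28, with 55 called lower and 1 higher. From 154.6 to 184.0 Mb of chromosome 1 the median of 159 genes was -0.28, with 18 called lower and 0 higher. Other long segments were lower on chromosomes 6 (69.7 to 170.6 Mb, median -0.21, 28 called lower) and 11 (71.4 to 134.3 Mb, median -0.21, 25 called lower) and higher on chromosome 10 (0.1 to 43.4 Mb, median 0.27, 14 called higher and 2 lower). Tested against their neighbours, 323 genes differed, 121 higher and 202 lower, of which 285 were among the 688. MTSS1, MYO10, TMTC1, ICAM1, MMP14, GLI3 and CDKN1A passed this test as well.

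**Figure D3:**
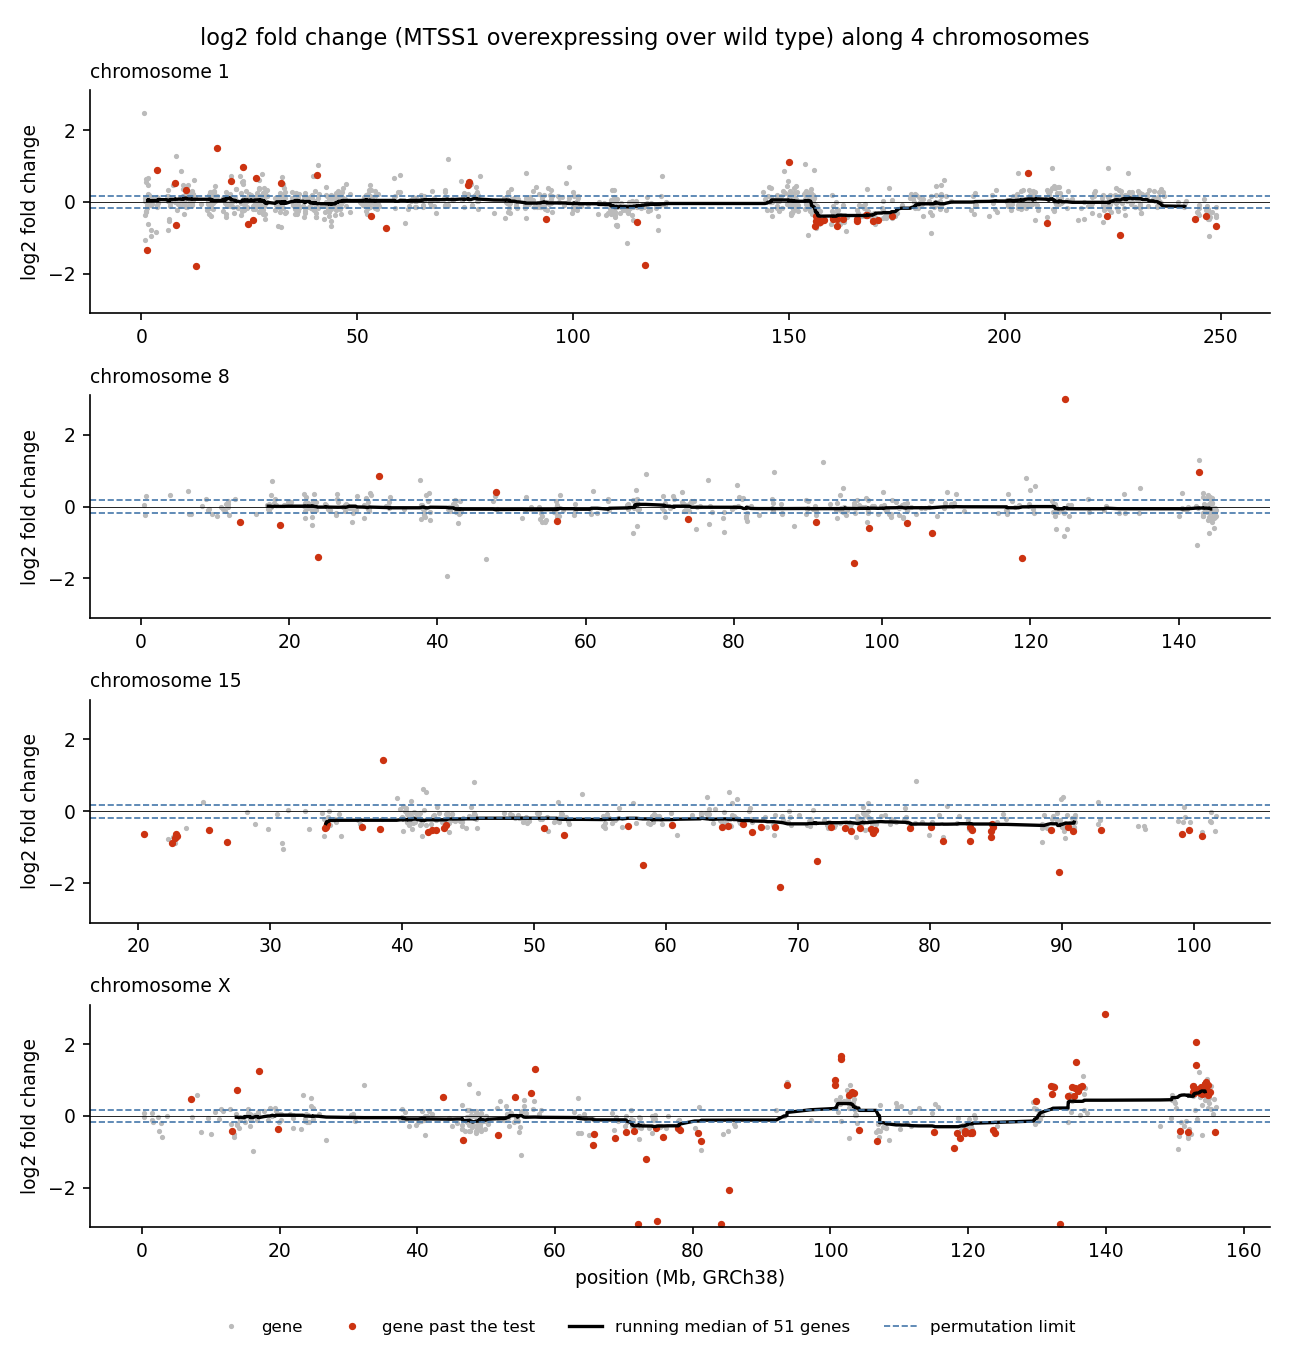
log2 fold change of MTSS1-overexpressing over wild type cells (vertical axes, values beyond 3 in either direction drawn at 3) against position in Mb on GRCh38 for genes with at least 2 CPM on chromosomes 1, 8, 15 and X. Red points are genes past edgeR's test, the black line is the running median of 51 genes and the dashed lines are the permutation limit of 0.17. Chromosome 15 lies below 0 over its length, chromosome 1 from 154.6 to 184.0 Mb lies below and distal X above 0, and chromosome 8, which holds MTSS1, has no segment past the limit.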

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

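The test against neighbouring genes and the fit without title numbers 2 and 3 were chosen after the data were seen, and the other alternatives before. With RLE size factors, a filter of at least 50 counts in 3 libraries and limma-voom, 684, 674 and 662 genes changed, and 682, 622 and 639 of the 688 calls kept their sign and call. MTSS1 kept its call in these fits, with no filter, with DESeq2, with the block and without title numbers 2 and 3, and its log2 fold change lay between 4.51 and 4.72 without 1 library.

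The count of changed genes was 1489 with no filter (679 higher, 810 lower), 1188 with DESeq2 (525 and 663) and 3651 with neighbouring title numbers as a block (1716 and 1935). It was 57 against a 1.5-fold change (14 and 43), 323 against neighbouring genes (121 and 202) and 132 without title numbers 2 and 3 (56 and 76). Without 1 library it lay between 145 and 346 (59 to 148 higher, 86 to 198 lower). The 1.5-fold test asks for more by construction and the fits without title numbers 2 and 3 or without 1 library hold fewer libraries. For the others the cause was not tested.

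Of 65 named calls, 24 were lost against neighbouring genes, 34 without title numbers 2 and 3, 1 with DESeq2, 4 with limma-voom and 19 to 36 without 1 library. With the block, RLE size factors, no filter or the filter of at least 50 counts, 0 were lost. Genes that a filter left untested are not counted as lost. The sign of IRAK1 turned against its neighbours (-0.0524, edgeR adjusted p = 0.88), whose own median of 0.73 is what that test subtracts.

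The NF-κB target list did not pass camera in any fit that was run, but its direction turned up with at least 50 counts in 3 libraries (camera adjusted p = 0.76, unadjusted 0.6304), with the block (0.78, unadjusted 0.7492) and without title numbers 2 and 3 (0.83, unadjusted 0.7973). Without 1 library its unadjusted value lay between 0.1329 and 0.997, in both directions. The cause was not tested. Of the 25 lists, 4 passed with the preset correlation, 0 with an estimated correlation, 0 by fry's directional test and between 1 and 4 without 1 library. In simulated data of this depth and spread the gene test found 36% of 1.5-fold and 58% of 2-fold changes, so smaller changes were often missed. These rates do not cover the lowest-expressed genes, which were not among those changed in the simulation.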

Other observations

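The search for chromosome segments and the count of whole-segment medians were chosen after the result was seen, and the other tests before theirs. Of the explanations, 1 is biological, a difference in gene copy number.

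In the 10 splits of the 6 libraries into 3 and 3, the real split gave 688 genes and the highest other split 0, so 1 of 10 was as large. Of these, 4 part all 3 pairs of neighbouring title numbers, as the real split does, and the other 3 of the 4 gave 0. All these counts come from the unblocked fit, and the splits were not run with the block. The splits are too few for a share under 0.05.

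Neighbouring genes moved together in 22 segments. After the trend on GC content and transcript length was removed, 22 of 22 still had a window of 51 genes past the permutation limit. The median over a whole segment was past it in 14 of 22 before and in the same 14 after, which argues against that trend as the whole cause. In 22 of 22 the median had 1 sign in all 3 pairs of neighbouring title numbers, but the segments were found from the mean of these pairs, so this decides nothing about batches. A candidate explanation is that gene copy number differs between the 2 cell populations, as when sorted and selected cells descend from few founders. Segments found from higher-expressed genes held in lower-expressed genes in 14 of 18, between the bounds set in advance (at least 0.8 for, under 0.5 against), and DNA was not measured, so it stays open.

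The 13 mitochondrially encoded transcripts had a median log2 fold change of 0.3588, and 0.3159 after the trend on GC content and transcript length was removed, which argues against that trend as the whole cause. The median was 0.2122, 0.54 and 0.29 in the 3 pairs, so the rise was not confined to 1 pair of these libraries. The transcripts are correlated, so 3 medians of 1 sign cannot exclude that the rise rests mostly on 1 pair. Their rise did not pass without wild type replicate 2 (camera adjusted p = 0.093) or MTSS1 overexpressing replicate 3 (0.083), or with an estimated correlation (adjusted p = 0.79), and what lies behind it stays open.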
